A study of Caenorhabditis elegans with 12 samples.

How the data were processed

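RNA-seq was made from whole young adult Caenorhabditis elegans of 3 genotypes, each carrying a different mutation of htz-1, the gene for the histone variant H2A.Z. Per the labels' protocols, animals were grown on OP50-1 bacteria, total RNA was extracted with a phenol reagent and a column kit, and libraries were prepared by SMART-Seq2, a full-length cDNA method that does not keep the strand, so reads from exons that overlap on opposite strands cannot be told apart. There were 4 libraries per allele and 12 in all, numbered 1 to 4 within each allele. The labels give the same number as a batch, so each of the 4 batches holds 1 library of each allele. Nothing in the labels says whether the libraries of an allele came from separate cultures, so the p-values measure the spread between these libraries, part of which may be technical.

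The deposited values are on a log2 scale, as regularized logarithms (rlog) of normalized counts per gene, in 1 table for all libraries, a transformation known here from the table's own name. The submitters' processing notes name kallisto 0.48 and the genome build WBcel235 without giving their roles. The size factors, filters and rlog settings are not given in the sources used here. The rlog transformation shrinks differences between libraries at low counts: the median range over libraries was 0.064 for genes with a mean rlog between 0 and 1, and 0.92 for genes with a mean between 7 and 8. Folds printed here are 2 to the power of an rlog difference, so they understate the change of low genes. Read counts were not analysed here, so the depth of each library is unknown and no counting interval is given.

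The table held 23991 genes, all matched by identifier to the Ensembl release 115 annotation of WBcel235, which supplied names, coordinates and chromosomes. Genes with a mean rlog of at least 3 were kept, which left 17540 and removed 6451. Among the kept genes, 158 shared all 12 values with another gene, as reads assigned equally to identical sequences would give. Such genes are uncertain wherever they are named, because their reads cannot be assigned to 1 copy, and each counts as a gene in the totals.

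Differences between alleles were tested with limma 3.58.1 in R 4.3.3, in 1 fit of all 12 libraries with a mean for each allele and no other term. The variance prior followed mean expression, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each difference is the first allele named minus the second. A gene was counted as equivalent when the 95% confidence interval of its difference lay within 1 log2 unit of 0 on both sides. The share of variance between alleles was tested by an exact permutation of allele labels within batches, one-sided, over 216 arrangements. Chromosomes were compared with two-sided Fisher's exact tests. Gene lists, 31 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and limma's fry as alternatives. Figures were drawn with matplotlib 3.10.9.

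The test, the samples, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names htz-1. For each pair of alleles it names up to 10 genes with the largest positive and 10 with the largest negative difference, among genes that passed the threshold and differed the same way in all 4 batches. For each list that passed its test or held at least 3 genes past the threshold, it names the 4 members with the smallest p-values. Genes named outside this rule are identified as such.

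Because the labels make the replicate number a batch, the numbers pair the libraries, and a fit with the batch as a replicate block was run beside the fit without it. Deviations from the allele means correlated between libraries of the same number with Pearson r from -0.32 to 0.48 (median 0.14, 12 pairs), against a median of -0.05 for 36 pairs of different numbers. In 4 of 12 libraries the closest partner carried the library's own number. Blocked results are given beside the counts of genes, the named genes and the lists they change, and not beside the chromosome tests. Other alternatives were no filter, a stricter filter, no variance trend, median centring, quantile normalization, library weights, batch as a random effect, only the libraries compared, and leaving out each library in turn. Those added after seeing the data left out 2 libraries together, used a molting score as a covariate, collapsed genes with identical values, or left out a repeated segment of chromosome V.

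The limma step was tested on simulated data made from these libraries' residuals, with 200 of 17540 genes changed in each of 20 simulations. For bon101 against ok3099 it recovered 32.4% of changes of 0.5 log2 units, 80.1% of changes of 1 unit and 96.1% of changes of 2 units, with a median of 2 wrong calls. For bon101 against tm2469 these shares were 33.4%, 79.8% and 96.0%, and for ok3099 against tm2469 34.3%, 79.4% and 95.5%, with medians of 2 and 4 wrong calls. The changes were added to rlog values, so the shrinkage of low genes was not simulated. The 200 changed genes also exceed the 42, 27 and 16 called in the data, which eases the adjustment, so these shares may be too high. When the cytosolic ribosome list alone was shifted by 0.5 log2 units between bon101 and ok3099, camera called it in 10 of 10 simulations. It also called a median of 6.5 unshifted lists, so calls by camera at the preset correlation are weak evidence here.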

Results

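The series compared 3 mutant alleles of htz-1, which encodes the histone variant H2A.Z, in whole young adult C. elegans: bon101, ok3099 and tm2469. Its stated purpose was to ask whether different mutations of the gene lead to similar expression across the genome. Each allele had 4 RNA-seq libraries, 1 per batch, and the values were rlog expression levels on a log2 scale. The median rlog of the 17540 kept genes lay between 8.07 and 8.18 in the 12 libraries. A wild-type library was not analysed here, so each result is a difference between mutants.

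The mutated gene itself separated the 3 alleles. The htz-1 transcript (WBGene00019947, chromosome IV, 4446216 to 4446999, plus strand, WBcel235) had an rlog level of 11.85 ± 0.08 in bon101, 10.27 ± 0.20 in tm2469 and 8.03 ± 0.17 in ok3099 (SD, n = 4). It was 14.1-fold higher in bon101 than in ok3099, with a log2 difference of 3.81 (SE 0.12) and an adjusted p of 1.24e-09 by limma. It was 2.97-fold higher in bon101 than in tm2469 (1.57, limma adjusted p = 3.21e-05) and 4.73-fold lower in ok3099 than in tm2469 (-2.24, limma adjusted p = 8.91e-07). No library of 1 allele reached the range of another. The labels do not say which part of the gene each allele removes or alters, so the transcript level checks the labels only in part.

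**Figure D1:**
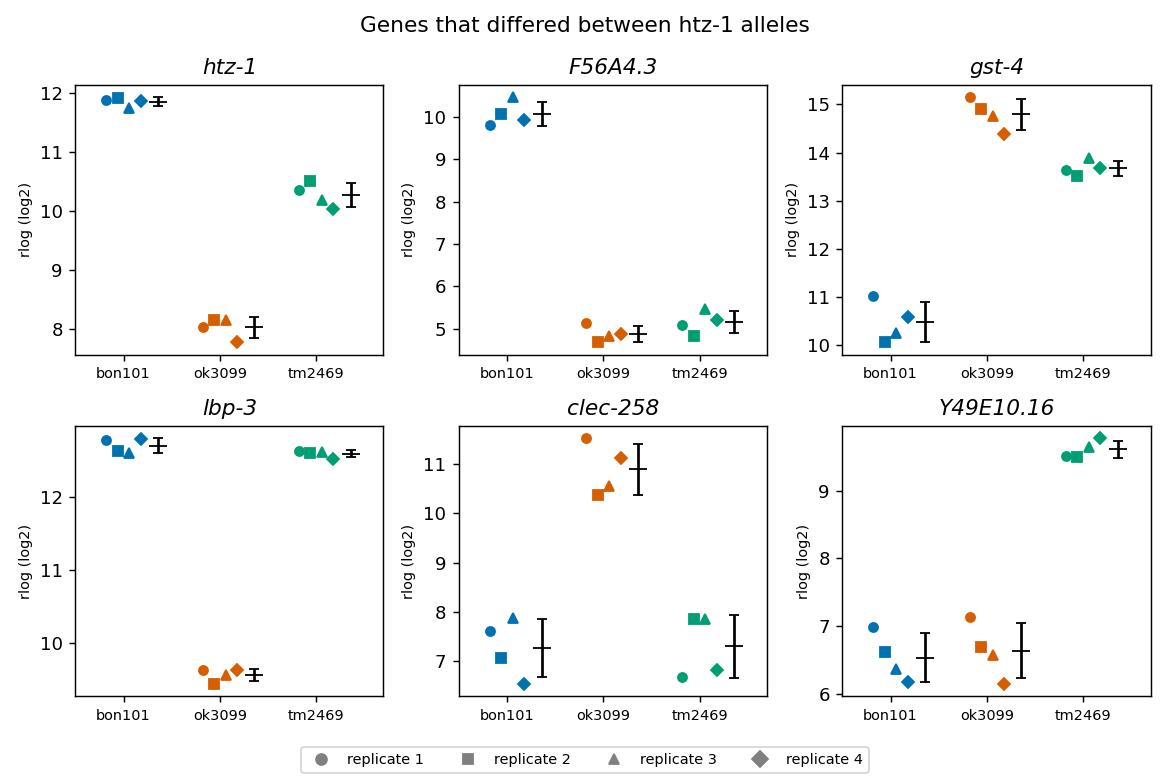
Expression level of 6 genes (rlog, log2 scale, vertical axis) in each library of the 3 htz-1 alleles (horizontal axis); coloured symbols are single libraries, with 1 symbol shape per replicate number, and the black bars are the mean and SD of 4 libraries. For htz-1 the bon101 libraries sit between 11.74 and 11.91, the tm2469 libraries between 10.04 and 10.51, and the ok3099 libraries between 7.78 and 8.16.

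Between bon101 and ok3099, genes of a short stretch of chromosome V and lbp-3 were higher in bon101, while gst-4, clec-258 and cyp-35B2 were lower. F56A4.3 (chromosome V, 2453414 to 2456147) was 36.3-fold higher in bon101, at 10.06 ± 0.28 against 4.88 ± 0.19 (SD, n = 4; limma adjusted p = 2.48e-09). The lipid-binding protein gene lbp-3 (chromosome X, 3257372 to 3258155) was 8.76-fold higher in bon101 (12.69 ± 0.10 against 9.56 ± 0.08; limma adjusted p = 9.46e-11), and the ABC transporter gene mrp-7 was 2.56-fold higher. The receptor L-domain gene irld-35 (chromosome V, 2348215 to 2350325) was 8.35-fold higher in bon101, by a log2 difference of 3.06 (limma adjusted p = 0.000174). The glutathione S-transferase gene gst-4 (chromosome IV, 10142225 to 10143099) was 19.9-fold lower in bon101 (10.48 ± 0.42 against 14.80 ± 0.32; limma adjusted p = 8.58e-08). The C-type lectin gene clec-258 was lower in bon101 by a log2 difference of -3.62 (limma adjusted p = 0.00045), and the cytochrome P450 gene cyp-35B2 was 3.09-fold lower.

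In that comparison 42 of 17540 genes passed the limma threshold after Benjamini-Hochberg adjustment, 21 higher and 21 lower in bon101, and 1241 had an unadjusted p under 0.05. Counting genes of identical values once leaves 38 of the 42. Centring each library on its median gave 36 genes, 22 of them higher (61.1% instead of 50.0%). Others higher in bon101 were K02F3.12 (1.35), the pseudogene WBGene00014955 (1.35), T04A11.4 (1.24) and both copies of Y19D10A.4 (1.23). Others lower in bon101 were H20E11.2 (-3.11), argk-1, an arginine kinase gene (-2.46), the chemoreceptor gene str-7 (-2.45), C17H12.6 (-1.66), nspa-8 (-1.57) and the kinesin gene klp-4 (-1.44). R08F11.4 was 4.01-fold lower. Each of these differed the same way in all 4 batches. With the batch as a block 25 genes passed, 24 of them among the 42; H20E11.2 (0.0595), argk-1 (0.0557), C17H12.6 (0.112), nspa-8 (0.0782), cnt-1 (0.0688), cdr-1 (0.0688), nhr-80 (0.0649) and both copies of F56A4.12 (0.0649), a gene named after its value was seen, then had limma adjusted p-values above the threshold. Leaving out bon101 replicate 1, bon101 replicate 2 or ok3099 replicate 1 left 24, 27 and 21 genes.

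Between bon101 and tm2469, the same stretch of chromosome V was again higher in bon101 and gst-4 again lower. F56A4.3 was 30.1-fold higher in bon101 (10.06 ± 0.28 against 5.15 ± 0.26, SD, n = 4; limma adjusted p = 1.44e-08). In that stretch, irld-35 (2.58), Y19D10A.4 (1.38), the C-type lectin gene clec-209 (1.37), the monocarboxylate transporter gene mct-2 (1.26) and C01B4.8 (1.16) were also higher. Y19D10A.4, clec-209 and C01B4.8 are uncertain, since the values of each were identical to those of a copy. The gst-4 transcript was 9.19-fold lower in bon101 than in tm2469 (limma adjusted p = 6.67e-06). Y49E10.16 (chromosome III, 12430509 to 12433866) was 8.40-fold lower in bon101, at 6.54 ± 0.36 against 9.61 ± 0.13 (SD, n = 4; limma adjusted p = 1.92e-05).

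There 27 genes passed the limma threshold, 17 higher and 10 lower in bon101, and 2242 had an unadjusted p under 0.05. Counting genes of identical values once leaves 22 of the 27. Of the 17 higher, 12 were entries of that stretch. Also among the 17 were both entries of the ribosomal RNA gene rrn-1.1 (0.76), identical in value and named after they were seen. With each library centred on its median 27 genes also passed, 20 of them higher (74.1% instead of 63.0%). Lower in bon101 were also klp-4 (-1.36), C33F10.4 (-1.24), H08M01.1 (-1.02), F35A5.1 (-0.80), the galectin gene lec-3 (-0.76), F36D3.8 (-0.71), the scaffold gene lin-2 (-0.69) and T24H10.5 (-0.67). With the batch as a block 25 genes passed, 23 of them among the 27. F35A5.1 (0.120), lin-2 (0.0873), T24H10.5 (0.0958) and pcf-11 (0.12), a gene named after its value was seen, then had limma adjusted p-values above the threshold. Without tm2469 replicate 1 the count was 795, with 657 genes lower in bon101, and these included all 27. That library stood apart from the others of its allele, so the 795 are not evidence of a difference.

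Between ok3099 and tm2469, lbp-3 and Y49E10.16 were lower in ok3099, and clec-258, cyp-35B2 and gst-38 were higher. The lbp-3 transcript was 8.13-fold lower in ok3099 (9.56 ± 0.08 against 12.58 ± 0.04, SD, n = 4; limma adjusted p = 1.46e-10), Y49E10.16 was 7.85-fold lower and mrp-7 was 2.34-fold lower. The clec-258 transcript was higher in ok3099 by a log2 difference of 3.59 (10.89 ± 0.52 against 7.30 ± 0.64; limma adjusted p = 0.000888). Higher in ok3099 were also cyp-35B2 (1.97), the glutathione S-transferase gene gst-38 (1.18) and the cadmium-responsive gene cdr-1 (1.06).

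In all 16 genes passed the limma threshold, 6 higher and 10 lower in ok3099, and 2588 had an unadjusted p under 0.05. Also lower in ok3099 were pei-1 (-2.13), F57F4.1 (-1.90), the P-glycoprotein gene pgp-6 (-1.47), H08M01.1 (-1.08), the ArfGAP gene cnt-1 (-0.74) and F08F8.6 (-0.70); R08F11.4 (4.01-fold) and C17H12.6 (1.72) were higher. With the batch as a block 10 genes passed, 9 of them among the 16; R08F11.4 (0.0709), C17H12.6 (0.0983), cdr-1 (0.0509), pei-1 (0.0851), F57F4.1 (0.0871), cnt-1 (0.0871) and F08F8.6 (0.0871) then had limma adjusted p-values above the threshold. Without tm2469 replicate 1 the count was 1415, 978 of them lower in ok3099, and these included all 16. As that library stood apart from its allele, the 1415 are not evidence of a difference. The calls of pgp-6 and H08M01.1, kept with the block, were each lost in 9 of the 12 fits without 1 library. Leaving out bon101 replicate 1, ok3099 replicate 1, 2 or 4, or tm2469 replicate 2, 3 or 4 gave 10, 8, 9, 7, 8, 8 and 10 genes.

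Some genes set 1 allele apart from both others. In bon101 these were 14 annotated genes higher and 3 lower than in both other alleles. Of the higher, 12 were entries of the short stretch of chromosome V, F56A4.3 and irld-35 among them. Both entries of clec-209, F56A4.12, C01B4.8 and Y19D10A.4 are counted there, although the entries of each have identical values. The other higher genes were K02F3.12 and htz-1, and gst-4, klp-4 and C33F10.4 were the lower. In ok3099 they were 6 higher, among them clec-258, cyp-35B2, gst-38 and cdr-1, and 4 lower: htz-1, lbp-3, mrp-7 and cnt-1. In tm2469 they were 2 higher genes, Y49E10.16 and H08M01.1. Each pair of comparisons shares the 4 libraries of 1 allele. In 100 simulations of unchanged alleles the largest overlap was 0. Those hold no changed gene, so they cannot show what the shared libraries add to the overlap of called genes. Independent lists of these sizes would share 0.02 genes or fewer, a value that ignores the shared libraries and the genes of identical values. With the shared libraries divided between the comparisons the overlaps were 9 to 12 for bon101, 3 to 4 for ok3099 and 1 for tm2469. With the batch as a block the 17 genes of bon101 became 15 and the 10 of ok3099 became 5 (lbp-3, mrp-7, clec-258, cyp-35B2 and htz-1), all among the former, while both genes of tm2469 stayed. The calls of H08M01.1 were less stable: in each of its comparisons 9 of the 12 fits without 1 library lost the call (limma adjusted p up to 0.137 against bon101 and 0.146 against ok3099), and those without bon101 replicate 3, ok3099 replicate 3 or tm2469 replicate 1 kept it.

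A test for any difference among the 3 alleles passed for 44 genes by limma's F test, and for 37 with the batch as a block, 32 of them among the 44. Without ok3099 replicate 1, ok3099 replicate 4 or tm2469 replicate 1 the count was 25, 27 and 1062. Most genes lay in a narrow interval around 0. The 95% interval of the difference stayed within 1 log2 unit for 16591 genes (94.6%) between bon101 and ok3099, 16189 (92.3%) between bon101 and tm2469 and 15979 (91.1%) between ok3099 and tm2469. Within 0.5 log2 units the shares were 69.2%, 66.4% and 65.8%. The rlog transformation draws low genes towards 0, which adds to these counts.

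Differences between alleles were only part of the variation between libraries. The most similar library belonged to another allele for 6 of the 12 libraries. Allele means held 32.2% of the variance over the kept genes, with an exact permutation p of 0.0139 (one-sided; the smallest possible was 0.00463) and a jackknife SE of 17.2 percentage points. Degrees of freedom alone would give alleles 18.2%. Batches held 27.3%, the share that degrees of freedom alone would give them. The first principal component held 52.3% of the variance and divided libraries within alleles. In tm2469, replicate 1 scored -22.8 and replicates 2 to 4 scored 39.4, 37.1 and 42.7. In bon101 the scores were -23.8, -31, 27.3 and -5.1 for replicates 1 to 4, and in ok3099 they lay between -36.0 and -0.5. Cuticle collagen genes such as col-133, col-129 and col-147 had the strongest positive loadings. Among the strongest negative ones were col-74, col-165, the lipocalin-related lpr-4 and the hedgehog-related wrt-1, and all 7 were named after their values were seen.

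**Figure D2:**
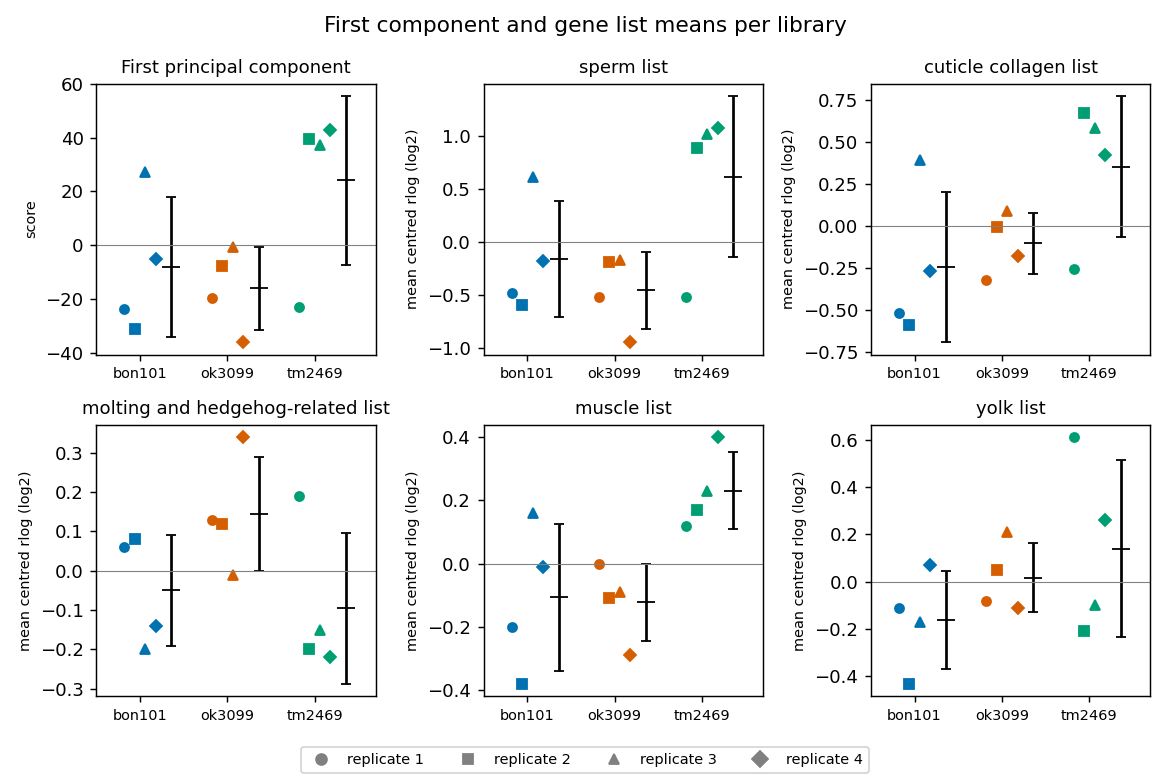
Score on the first principal component and mean centred expression (rlog, log2 scale) of 5 gene lists in each library of the 3 htz-1 alleles; coloured symbols are single libraries, with 1 symbol shape per replicate number, and black bars are the mean and SD of 4 libraries. The sperm list had means of 0.89, 1.02 and 1.08 in tm2469 replicates 2 to 4 and 0.61 in bon101 replicate 3, against -0.52 in tm2469 replicate 1.

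Sperm genes had lower mean levels in bon101 and ok3099 than in tm2469, without passing the test gene by gene. The list of 85 kept sperm genes (major sperm protein, spe and related families) had a median difference of -1.34 between ok3099 and tm2469 and -0.93 between bon101 and tm2469, and 81 and 79 of its members had negative differences. Between ok3099 and tm2469, 63 members passed limma's test when adjusted over the list alone and 0 over all genes (66 at an unadjusted p under 0.05); ssp-16 (-1.44), spe-8 (-0.91), spe-54 (-1.06) and spe-18 (-1.70) had the smallest p-values. By limma's camera the adjusted p was 9.07e-25 for ok3099 against tm2469 and 1.2e-13 for bon101 against tm2469, but these were adjusted p = 0.652 and adjusted p = 0.687 with an estimated correlation. Between bon101 and ok3099 the median was 0.33, with camera adjusted p = 7.34e-05 and adjusted p = 0.678 with an estimated correlation. Without tm2469 replicate 1, 65 sperm genes passed limma's test over all genes as lower in ok3099 than in tm2469, and 56 as lower in bon101. The list medians in these comparisons were then -1.83 and -1.41. The library left out stood apart on this very list, so these counts and medians are not evidence of a difference. Within bon101 the sperm list mean was 0.61 in replicate 3 and -0.48, -0.60 and -0.18 in replicates 1, 2 and 4. In ok3099 replicates 1 to 4 it was -0.52, -0.19, -0.17 and -0.95, so of the bon101 libraries only replicate 3 lay above the ok3099 range. The mean of the molting list was also used as a covariate, a setting chosen after seeing the data. The sperm medians were then -0.29 between ok3099 and tm2469, -0.73 between bon101 and tm2469 and -0.44 between bon101 and ok3099. The last thus changed direction. With the covariate 30 of the 85 sperm genes passed over all genes as lower in bon101 than in tm2469, and 0 in the other comparisons.

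Collagen, muscle, intestine and respiratory-chain lists had medians on the side of higher expression in tm2469, and their calls by camera did not hold with an estimated correlation. Of 146 cuticle collagens, all but 31 had negative differences between bon101 and tm2469 (median -0.32, camera adjusted p = 2.74e-07 by limma) and all but 41 between ok3099 and tm2469 (median -0.26, 0.000826), and these were adjusted p = 0.681 and adjusted p = 0.698 with an estimated correlation. All 23 muscle genes, tnt-2 and unc-15 among them, had negative differences in both comparisons (medians -0.32 and -0.35; camera adjusted p = 6.18e-08 and 2.75e-09 by limma; adjusted p = 0.681 and adjusted p = 0.652 with an estimated correlation). For muscle 9 members passed between ok3099 and tm2469 when adjusted over the list alone and 0 over all genes (12 at an unadjusted p under 0.05). The nuclear-encoded oxidative phosphorylation list had medians of -0.20 and -0.22 (camera adjusted p = 7.81e-05 and 2.98e-06 by limma; adjusted p = 0.687 and adjusted p = 0.698 with an estimated correlation). Between bon101 and tm2469 the intestine list (median -0.42, asp-1 -0.57, cpr-5 -0.99), the lipid metabolism list (median -0.07, fat-7 -1.38, nhr-80 -0.81) and the endoplasmic reticulum stress list (median -0.10, hsp-3 -0.26) had camera adjusted p of 0.00337, 0.0166 and 0.0213 by limma. These were adjusted p = 0.687, adjusted p = 0.423 and adjusted p = 0.687 with an estimated correlation. Of these 3 lists 0 members passed limma's test over all genes, with 6, 18 and 3 members at an unadjusted p under 0.05. Without tm2469 replicate 1, 10 lipid metabolism genes and 14 collagens passed as lower in bon101 than in tm2469. Of the intestine and endoplasmic reticulum stress lists 0 members did. Between ok3099 and tm2469, 14 collagens and 5 muscle genes then passed as lower in ok3099, and 7 collagens as higher. Since tm2469 replicate 1 stood apart from its allele, these counts without it are not evidence of a difference. The intestine list between ok3099 and tm2469 had a camera adjusted p of 0.0692 by limma and 0.0487 with the batch as a block, and adjusted p = 0.802 with an estimated correlation. Mean collagen expression was 0.67, 0.58 and 0.42 in tm2469 replicates 2 to 4 and 0.39 in bon101 replicate 3, against -0.26 in tm2469 replicate 1. Under the molting covariate the medians between ok3099 and tm2469 were -0.01 for collagens, -0.16 for muscle, -0.01 for oxidative phosphorylation and 0.03 for intestine, and camera no longer called the collagen and oxidative phosphorylation lists there.

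The molting and detoxification lists had medians on the side of higher expression in ok3099, called by camera at the preset correlation but not with an estimated one. Of 59 molting and hedgehog-related genes 43 had negative differences between bon101 and ok3099 (median -0.13, camera adjusted p = 0.00107 by limma; adjusted p = 0.607 with an estimated correlation) and 37 had positive differences between ok3099 and tm2469 (median 0.10, camera adjusted p = 0.00241 by limma; adjusted p = 0.698 with an estimated correlation). The smallest p-values between ok3099 and tm2469 were those of wrt-3 (0.71), mlt-9 (1.10), wrt-10 (1.56) and grl-5 (0.93), and 0 members passed over all genes (15 at an unadjusted p under 0.05). Without tm2469 replicate 1, which stood apart from its allele, 8 members passed there as higher in ok3099 and 1 as lower. Such counts are not evidence of a difference. Of 177 detoxification genes 4 passed between bon101 and ok3099 over all genes, gst-4, cyp-35B2 and gst-38 lower and the glucuronosyltransferase gene ugt-64 higher (0.92) in bon101, and 16 when adjusted over the list alone, 12 lower and 4 higher. The detoxification list had medians of -0.08 between bon101 and ok3099 and 0.06 between ok3099 and tm2469 (camera adjusted p = 0.00369 and 0.00574 by limma; adjusted p = 0.607 and adjusted p = 0.652 with an estimated correlation). With the batch as a block gst-38 and ugt-64 both had a limma adjusted p of 0.0649 between bon101 and ok3099. Mean molting-list expression was 0.19 in tm2469 replicate 1 and -0.20, -0.15 and -0.22 in replicates 2 to 4, and it was 0.34 in ok3099 replicate 4. Used as the covariate, the molting list itself had medians of -0.03 between bon101 and ok3099 and 0.01 between ok3099 and tm2469, which the covariate makes small by construction, and camera did not call it there.

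Ribosomal, histone, germline and heat shock lists had small median differences between bon101 and ok3099, called by camera at the preset correlation but not with an estimated one. Of 80 cytosolic ribosomal protein genes, 79 had positive differences there (median 0.13, camera adjusted p = 3.21e-17 by limma; adjusted p = 0.607 with an estimated correlation) and 75 had negative differences between ok3099 and tm2469 (median -0.11, 1.22e-06; adjusted p = 0.831 with an estimated correlation). Histone genes other than htz-1 (median 0.08), oocyte and early embryo genes (0.10), mitotic and meiotic germline genes (0.08) and heat shock genes (0.10) had positive medians there, with camera adjusted p of 0.00717, 7.34e-05, 0.0314 and 0.00286 by limma. With an estimated correlation these were adjusted p = 0.607, adjusted p = 0.607, adjusted p = 0.678 and adjusted p = 0.607. The endoplasmic reticulum stress list had a median of -0.08 there (camera adjusted p = 0.0314 by limma; adjusted p = 0.678 with an estimated correlation). In these lists 0 members passed limma's test over all genes, with 9 ribosomal, 8 histone and 3 heat shock genes at an unadjusted p under 0.05; his-61 (0.39), egg-2 (0.22), zim-1 (-0.25, against the direction of its germline list), hsp-16.1 (0.28) and rpl-7A (0.21) were among those with the smallest p-values. The innate immunity list, whose camera adjusted p was 0.840 between bon101 and ok3099, had 3 of 233 members past limma's threshold there, both entries of clec-209 higher and clec-258 lower in bon101, and 7 when adjusted over the list alone. Mean ribosomal expression was -0.28 in ok3099 replicate 4 and between -0.03 and 0.02 in the other ok3099 libraries. In bon101 replicates 1 to 4 it was -0.03, 0.03, 0.08 and 0.12, so the ribosomal differences rest in part on ok3099 replicate 4. Under the molting covariate the ribosomal medians were 0.05 between bon101 and ok3099 and -0.01 between ok3099 and tm2469, and camera did not call the latter. The histone and germline medians were 0.01 and 0.03 between bon101 and ok3099, and these lists and the endoplasmic reticulum stress list were not called there.

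The genes past the threshold were concentrated on chromosome V. Between bon101 and ok3099, 25 of 42 lay on V, where 20.9% of the kept genes lie (odds ratio 5.60, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.31e-06), and between bon101 and tm2469 13 of 27 (odds ratio 3.53, adjusted p = 0.0173, exact). Between ok3099 and tm2469, 7 of 16 lay on V (odds ratio 2.95, adjusted p = 0.272, exact). In each comparison with bon101, 12 of these genes came from a segment of V between 2348215 and 2560739, in which the annotation lists 19 pairs of genes of the same name at a median offset of 108279 bases. Without the segment the odds ratios were 2.93, 0.272 and 2.97, with adjusted p of 0.126, 1 and 0.386 (Fisher's exact test). Apart from htz-1, 0 of the 682 kept genes within 2 Mb of htz-1 passed in any of the 3 comparisons by limma. So few calls decide little (p = 0.409 and 0.625 by Fisher's exact test in the comparisons with bon101). With a window of 4 Mb the counts were 2, 0 and 1. Within 2 Mb, 39, 114 and 148 genes had an unadjusted p under 0.05, against 1241, 2242 and 2588 of all 17540. The last 2 shares were above those over all genes and the first below, which was not tested.

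Inside the segment 16 genes had a mean rlog of at least 5, and 12 of them passed the limma threshold as higher in bon101 in each comparison with it; with the batch as a block 10 passed against ok3099 and 12 against tm2469. All 16 had positive differences there, also with median centring and quantile normalization. Their median difference was 1.08 against ok3099 and 1.16 against tm2469, and 0.09 between ok3099 and tm2469. The 20 such genes before the segment had a median of 0.01 between bon101 and ok3099, and the 20 after it -0.08, with 0 past the limma threshold. The annotated copies of clec-209, F56A4.12, C01B4.8, Y19D10A.4 and C01B4.6 had identical values in every library, so 10 of the 16 genes are 5 measurements; C01B4.6 was named after its values were seen. F56A4.3, with the largest difference, lies between the copies, which end at 2452460 and begin again at 2456176.

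**Figure D3:**
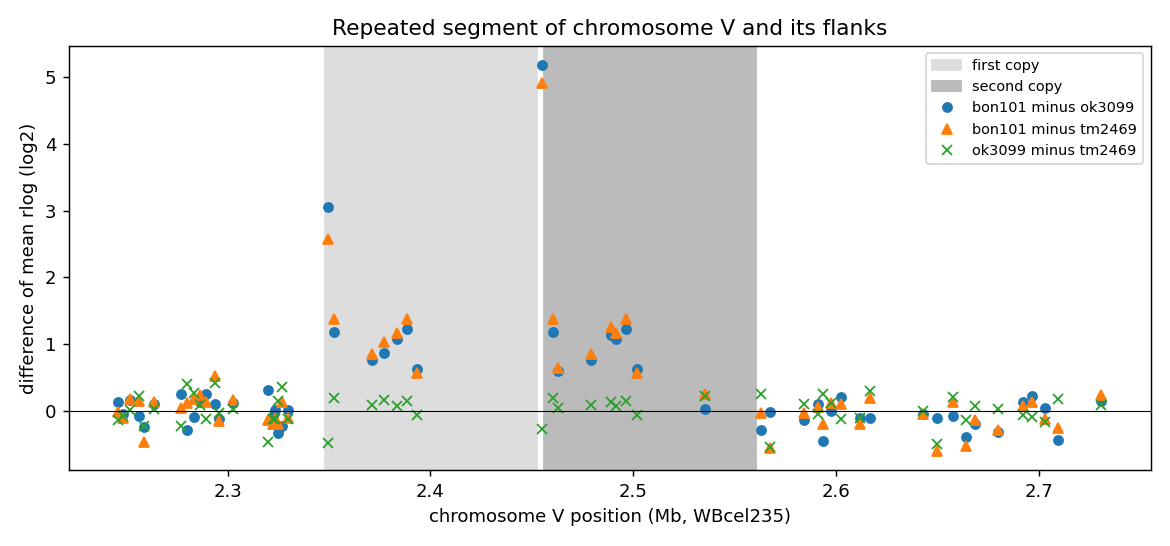
Difference of mean rlog (log2 scale, vertical axis) of genes with a mean rlog of at least 5 along chromosome V (position in Mb, WBcel235), for the 3 pairs of alleles; the shaded bands are the copies of the repeated segment. The 16 genes in the segment have a median of 1.08 for bon101 minus ok3099, against 0.01 and -0.08 for the 20 genes on either side.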

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

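All tests of explanations in this part were chosen after the results they bear on were seen, except the comparisons with other splits of the libraries, which were planned.

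Samples far from the others of their allele were looked for in 447 groups of 4 libraries, where chance flags about 1 in 20, or 22.4 groups. In 34 groups 1 library lay far from the other 3, and in 12 of these it was tm2469 replicate 1. That library was apart on the first component (-22.80) and on the sperm list mean (-0.52), and low for nspa-8 (9.26), ssp-16 (9.33), rps-6 (13.96), rpl-12 (17.35), mct-2 (9.19), col-166 (12.47), acs-18 (7.71) and fat-7 (10.34). It was high for col-43 (9.66) and col-95 (16.16). In bon101 replicate 3, col-95 was low (15.03) and H08M01.1 high (5.81).

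The other 20 were spread over libraries. In tm2469 replicate 3, Y19D10A.4 was low (8.83, both copies) and gst-38 high (8.29), and in tm2469 replicate 4 K02F3.12 was high (10.73). In ok3099 replicate 4, rpl-12 (17.22), mup-2 (11.61), the histone list mean (-0.15) and the ribosome list mean (-0.28) were low, and lec-3 (9.31) and col-34 (10.63) high. In ok3099 replicate 3, spe-44 (7.99) and myo-1 (9.15) were low and H08M01.1 (5.63), pei-1 (6.42) and col-43 (10.57) high, and in ok3099 replicate 2 ugt-64 was high (10.81). In bon101, replicate 1 was low for oma-2 (13.62) and high for the dosage compensation list mean (0.04), replicate 2 was high for grl-24 (3.06) and replicate 4 low for nuo-2 (10.32).

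The first pattern is that tm2469 replicates 2 to 4 and bon101 replicate 3 stood apart from the other 8 libraries on the first component. Exchanged labels of bon101 replicate 3 and tm2469 replicate 1 are argued against, since htz-1 in bon101 replicate 3 lay 1.23 log2 units from the nearest tm2469 library. The labelled batches are argued against as the whole cause, since in 1 of the 4 batches all 3 libraries lay on the same side of 0. Animals collected at different points around the last molt remain a candidate explanation: among the other 8 libraries the molting and sperm list means had Pearson r = -0.82 (exact permutation p = 0.0173, adjusted over 2 relations 0.0345) and Spearman rho = -0.76 (exact p = 0.0368), but without the 2 libraries farthest from the median r was -0.47, so the relation rests on those libraries. The yolk list did not move with the molting list there (r = 0.01, exact permutation p = 0.981), no batch holds enough of the 8 libraries for a value of its own, and a difference between alleles in the pace of development was not tested.

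The second pattern is the higher level of genes of the repeated chromosome V segment in bon101. In genes with a same-named copy, shared reads leave open which copy differed. Only 2 of the 16 segment genes had no such copy, F56A4.3 at 5.18 and Y45G12C.10 at 0.03 from ok3099. Pairs of copies with identical values were all higher in bon101, from 0.63 (C01B4.6) to 1.23 (Y19D10A.4) above ok3099. Sharing divides reads within a library and would not by itself raise both entries in 1 allele. That argues against sharing as the sole cause for these pairs. The 6 segment genes that shared their values with no other gene had medians of 1 from ok3099 and 1.15 from tm2469. All 6 were positive, and 4 passed the limma threshold in each comparison. Copies that differ in value can still share reads, but the difference is not confined to genes with identical values. More copies of the segment in bon101 than in the other strains could account for it: the segment genes had a median difference of 1.08, near the 1 log2 unit that 2 copies against 1 would give, and F56A4.3, which lies between the copies, was at 4.88 in ok3099 and 5.15 in tm2469 against 10.06 in bon101. Inside the copies irld-35, at 3.06 from ok3099 and 2.58 from tm2469, and Y45G12C.10, named after its value was seen, depart from that value. DNA copy number was not measured, so a difference in strain background and a regional effect of the allele on transcription both stay open.

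Other splits of the libraries bear on whether the counts could arise by chance. Between bon101 and ok3099, 1 of 35 splits, the real one, gave as many as 42 genes, and the highest other gave 1. This argues against chance, but 1 of 35 is the smallest share these splits can give, and they do not keep the batches paired. Between bon101 and tm2469, 2 of 35 splits gave as many as 27, and the highest other gave 2455; between ok3099 and tm2469, 2 of 35 gave as many as 16, and the highest other gave 185, so chance is not excluded by this count. Those other splits put tm2469 replicate 1 with bon101 replicates 1, 2 and 4, or with ok3099 replicates 1, 2 and 4, which points to the structure of the first component rather than to the alleles. Among the 8 splits that part all 4 pairs of a batch, 1 gave as many genes in each comparison, the real one, and the highest others gave 1, 0 and 1; 8 splits are too few for a share under 0.05. For any difference among the alleles, 1 of 100 arrangements, the real one, gave as many as 44, and the highest other gave 22.

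Chance was also not excluded for the gene lists or for equivalence. As many lists as the real 9, 7 and 7 were called by camera in 10, 11 and 21 of 35 splits, with highest others of 15, 11 and 17. As few equivalent genes as the real 16591, 16189 and 15979 were found in 10, 5 and 4 of 35 splits, with lowest others of 16321, 15828 and 15814.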

How the results depend on the processing

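The alternatives that left out 2 libraries, used the molting covariate, collapsed identical genes or left out the chromosome V segment were chosen after seeing the data. The htz-1 differences kept their direction and their side of the threshold under each alternative run. Counts of equivalent genes and the share of variance between alleles have no direction to keep, and the permutation test of the share was not repeated under the alternatives. The share of variance lay between 28.1 and 47.7% with 1 library left out. With the replicate block, genes called fell to 25 between bon101 and ok3099 and to 10 between ok3099 and tm2469; besides the calls listed in the results it ended no call of a named gene, and it changed no call of a list except that of intestine between ok3099 and tm2469. With no filter on low values 10 genes were called between ok3099 and tm2469, where more genes share the adjustment. Library weights gave 41 genes between bon101 and tm2469, 990 between ok3099 and tm2469 and 291 for any difference; tm2469 replicate 1 had the lowest weight, 0.44. Leaving out 1 library gave 21 to 46 genes between bon101 and ok3099, 19 to 795 between bon101 and tm2469, 7 to 1415 between ok3099 and tm2469 and 25 to 1062 for any difference, and each highest value was the one without tm2469 replicate 1. Without bon101 replicate 3 and tm2469 replicate 1 together the counts were 2118, 1840 and 1996 for the last 3. Those libraries were chosen for standing apart, so these counts are not evidence of a difference. The same limit holds for the counts without tm2469 replicate 1 alone. Of 57 calls of named genes, 33 were kept in all 12 fits without 1 library, those of gst-4, lbp-3, mrp-7, clec-258, cyp-35B2, F56A4.3 and Y49E10.16 in every comparison where they were called among them. The calls of argk-1, nspa-8, F08F8.6 and F57F4.1 were lost in 10 of the 12, and those of H08M01.1, F35A5.1, pgp-6 and ugt-64, and of C17H12.6 and R08F11.4 between ok3099 and tm2469, in 9.

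With the molting covariate 218 genes were called between bon101 and ok3099, 325 between bon101 and tm2469 and 347 for any difference, but 12 between ok3099 and tm2469, 9 of them among the 16, and 4 lists there. As the mean of a list minus the mean of all genes, it turned sperm between bon101 and ok3099 from 0.31 to -0.33, and collagen and ribosome between ok3099 and tm2469 from -0.43 and -0.08 to 0.01 and 0.02. By the median only sperm turned among these (-0.44), since collagen and ribosome were both at -0.01, and the sperm median between ok3099 and tm2469 shrank from -1.34 to -0.29. With an estimated inter-gene correlation, and with fry, 0 lists were called in each comparison; unadjusted p-values under 0.05 numbered 1, 1 and 2 lists with the estimated correlation and 2, 4 and 5 with fry. Chromosome tests past the threshold, in either direction, numbered 4 with a mean rlog of at least 5 and 0 without the repeated segment, against 2. The odds ratio of V between bon101 and tm2469 turned to 0.272, since the segment held 12 of the 13 genes. Except where a cause is given, the cause was not tested. Over 4064 other values of named genes and lists, 3631 kept their side of the threshold, 313 lost the threshold, 116 passed it newly and 4 turned. A change of direction was counted only where a value passed the threshold, so the 3631 may include changes of direction among values that did not pass. Depth is unknown for these libraries, and rlog shrinkage limits what low genes can show.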

Other observations

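The tests of neighbouring genes in this part were chosen after the results were seen, and those of the gene lists were planned.

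Lists tied to H2A.Z biology and to lifespan had medians close to 0, which can hide members that differ in opposite directions. The list of H2A.Z deposition genes had median differences of 0.06, 0.10 and 0.03 for bon101 minus ok3099, bon101 minus tm2469 and ok3099 minus tm2469, with camera adjusted p of 0.345, 0.177 and 0.654 by limma, and 0 of 10 members passed over all genes. The synMuv B and DREAM list had medians of 0.02, -0.01 and -0.01, and the histone methylation list -0.02, 0.02 and 0.05. The DAF-16 and longevity list, 24 genes, had medians of 0.00, 0.01 and 0.05 (camera adjusted p = 0.840, 0.827 and 0.756 by limma). Between bon101 and tm2469, 5 of its members were higher and 4 lower in bon101 at an unadjusted limma p under 0.05, against 2242 of all 17540 genes. Between bon101 and ok3099 these were 1 and 1, and between ok3099 and tm2469 2 and 3. Over all genes 0 of its members passed in each comparison. The 12 genes of the mitochondrial genome had medians of 0.01, 0.05 and 0.04. With 1 library left out the medians of these 5 lists lay between -0.05 and 0.14, and some changed sign. Yolk genes had medians of -0.16, -0.22 and -0.05; without tm2469 replicate 1, whose yolk mean was 0.61, the last 2 were -0.03 and 0.13, and over all fits without 1 library they lay from -0.24 to -0.10, from -0.35 to -0.03 and from -0.18 to 0.13.

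Genes higher in ok3099 lay next to each other more often than in random draws. Outside the repeated segment 30 genes were called between bon101 and ok3099, and 7 of them had another within 10 kb: C17H12.6 with H20E11.2 on chromosome IV, gst-38 with cdr-1 on V, and F22B8.7, str-7 and argk-1 on V between 16094584 and 16105952. All 7 were lower in bon101, and F22B8.7 is named here after its value was seen. With the batch as a block only F22B8.7 and str-7 of the 7 were still called; these 2 lay within 10 kb among 15 such genes, as many as in 314 of 10000 draws (permutation p = 0.0315). Random placement is argued against, since 0 of 10000 draws of 30 kept genes gave as many (permutation p = 1e-04, the smallest these draws can give; highest 6), while between ok3099 and tm2469 gst-38 and cdr-1 made 2 of 16, as many as in 345 draws. Overlapping annotation is argued against, since 0 of the 4 neighbouring pairs overlap. Reads shared between near-identical neighbours cannot be told apart from this: 0 of the 7 genes shared their values with another gene, but sequences were not analysed here, and local differences between the strains, which may also account for it, were not tested.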
